A study of Mus musculus with 3 samples.

How the data were processed

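Epididymis RNA from 3 groups of male ICR mice was sequenced on libraries made with standard Illumina protocols after column extraction of tissue RNA, per the labels' protocols. The groups were Sham (3 mice), castrated mice given corn oil (Cas+CO, 5 mice) and castrated mice given testosterone propionate (Cas+T, 5 mice), each with 1 library. Whether a library pools all mice of its group, the number of vehicle injections, the read length and the strandedness are not given in the sources used here. The aligner, the counting tool and the genome build are likewise not given in the sources used here.

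The deposited files hold 1 value per gene on a log2 scale. The values were worked out from the files, since no header or label names their unit: 2 raised to the value, minus 1, gave multiples of 0.01 for 100% of the values under 1000 (within 0.001 of a step) and summed to 1000000 in every library. The deposited log2 values were therefore read as log2(TPM + 1). TPM was preferred to a unit without gene length because the lowest values depended on gene length: in Sham, the 1st percentile of values above 0 was 0.303 TPM for genes with under 500 exonic bases and 0.02 TPM for genes with over 5000. TPM is computed from read counts, gene length and the library total, so it keeps neither the depth nor the counting error. A loss of a few very abundant transcripts raises the TPM of every other gene, and a value of exactly 0 may be a failed estimate as well as an absence of reads. A TPM of 0 below means listed at 0, and no fold is printed against it. Such genes still enter the counts of higher and lower genes. In Cas+CO against Sham they made up 557 of the 7124 genes at least 2-fold apart.

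The files pair Ensembl identifiers with symbols, except for 937 of 23538 genes. Identifiers were looked up in the GENCODE M21 annotation (GRCm38) and the name table that goes with it: 23518 matched and 20 did not. Symbols held by more than 1 row (19) were summed, which left 23519. Coordinates are those of GENCODE M21 for the same identifiers, and no coordinates came from the deposited files.

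Log2 ratios were differences of log2(TPM + 1), with a pseudocount of 1, for genes that reached 1 TPM in at least 1 of the 2 libraries. Such ratios understate the change of low genes. A gene was counted as higher or lower at a ratio of at least 2-fold. With 1 library per group no test across samples exists, no p-value is given, and every ratio compares 2 libraries and not 2 conditions. Return after testosterone was the difference between Cas+T and Cas+CO divided by that between Sham and Cas+CO, both on the log2 scale. Because Cas+CO enters both, 100 sets of 3 libraries with no difference between groups were simulated. Their scatter was set per expression level from the deposited Cas+T and Sham values (median SD 0.21 on the log2 scale).

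Before the data were examined, 38 gene lists were fixed, covering secretory families of the epididymis, segment and cell type markers including other tissues, and cellular pathways. Each list's median log2 ratio was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. The random range runs from the 2.5 to the 97.5 percentile and describes these libraries, not the population of mice; lists with fewer than 3 members compared were left out. The genes named were fixed by rule at the same time. The rule took 10 anchor genes; the 10 largest rises and 10 largest falls of each comparison (5 and 5 for Cas+T against Sham) among genes with a proper symbol that reached 10 TPM; up to 4 members per list and comparison with the largest ratios; the 10 most abundant genes of each library; and the genes with the largest castration differences that did or did not come back. Of the genes this rule gave, 2 are not reported here. Other genes were named after their values were seen: Lcn2, Defb42, Etv5, Ly6g5b, Rnase11, Rnase12, Teddm2 and Hist2h2aa1.

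The scripts were tested on simulated data first. For Cas+CO against Sham with 23519 genes, all 100 genes lowered 2.83-fold and all 100 genes lowered 8-fold were found, and 0 of 14966 unchanged genes passed the limit. The scatter put on these data was an SD of 0.1 on the log2 scale, under the median of 0.21 taken from the deposited values. The lowered genes had a mean of 10 TPM or more. This checks the code, not how often unaltered genes pass the limit. At the wider scatter about 94.8 unaltered genes passed it as lower and 93.2 as higher. Alternatives fixed beforehand were a pseudocount of 0.1, no minimum, a minimum of 10 TPM, scaling to the median of expressed genes, scaling to the total without the 50 most abundant genes of any library, removal of sperm, blood, mitochondrial and ribosomal genes, a 4-fold limit, the highest row per symbol and a return of 75%. An alternative for raw counts could not be run on TPM values. Leaving out genes listed at 0 was added after the data were seen. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and Biopython 1.88.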

Results

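The epididymis, the duct in which sperm mature after they leave the testis, was profiled by RNA sequencing in adult male ICR mice (an outbred strain) with and without their testes. The study allotted 13 mice to 3 groups. The Sham group of 3 mice had surgery that left the testes in place. The other 10 mice were castrated on both sides with the epididymides kept, and treatment began 14 days later. Of these, 5 mice received corn oil (Cas+CO), and 5 received testosterone propionate, an injectable ester of testosterone, dissolved in corn oil at 5 mg/kg on 10 days in a row (Cas+T). Each group is represented by 1 library, and the labels do not say how many of its mice the library holds. There was therefore no replicate error for any value: each ratio compares 2 libraries, and none carries a test across animals.

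Expression values were TPM (transcript abundance scaled to gene length and to a fixed library total), which keep no record of sequencing depth, so the depth is unknown and no counting interval is given. The files listed 23538 genes. At 1 TPM or more there were 13702 genes in Sham, 15485 in Cas+CO and 14032 in Cas+T. The median gene stood at 2.27 TPM in Sham, 5.04 in Cas+CO and 2.83 in Cas+T. The 10 most abundant genes held 26.2% of all TPM in Sham, 21.6% in Cas+CO and 21.8% in Cas+T. Mitochondrially encoded genes held 13.2%, 12.5% and 11.01%, with mt-Atp8, a subunit of the mitochondrial ATP synthase, first in all 3 libraries. Nuclear copies of mitochondrial genes on chromosome 1 were listed with another 9.25%, 8.001% and 7.66%. How reads were divided between the mitochondrial genes and these copies is not known, so part of this share may belong to the mitochondrial genes.

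The anchor genes reported here, fixed before the data were examined, all differed at least 2-fold between Sham and Cas+CO. In Cas+T they ranged from near the Sham level (Rhox5, Gpx5) to listed at 0 (Prm2). Rhox5, an androgen-regulated homeobox gene, was at 4.79 TPM in Sham, listed at 0 in Cas+CO and at 4.72 TPM in Cas+T. Crisp1 (ENSMUSG00000025431), a secreted protein that binds to sperm, was at 44116, 6654 and 32799 TPM. Gpx5 (ENSMUSG00000004344), a secreted glutathione peroxidase, was at 17098, 335 and 15470 TPM, 51.1-fold lower in Cas+CO than in Sham. Adam7, a membrane protein transferred to sperm, was at 4633, 13.6 and 2825 TPM. Ros1, a receptor tyrosine kinase of the initial segment, was at 25.9, 11.9 and 15.0 TPM. Prm2, which packs DNA in sperm heads, was at 18.3 TPM in Sham and listed at 0 in both castrated libraries. Clu, the secreted chaperone clusterin, went the other way, with 8368 TPM in Sham, 25834 in Cas+CO and 12333 in Cas+T.

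**Figure D1:**
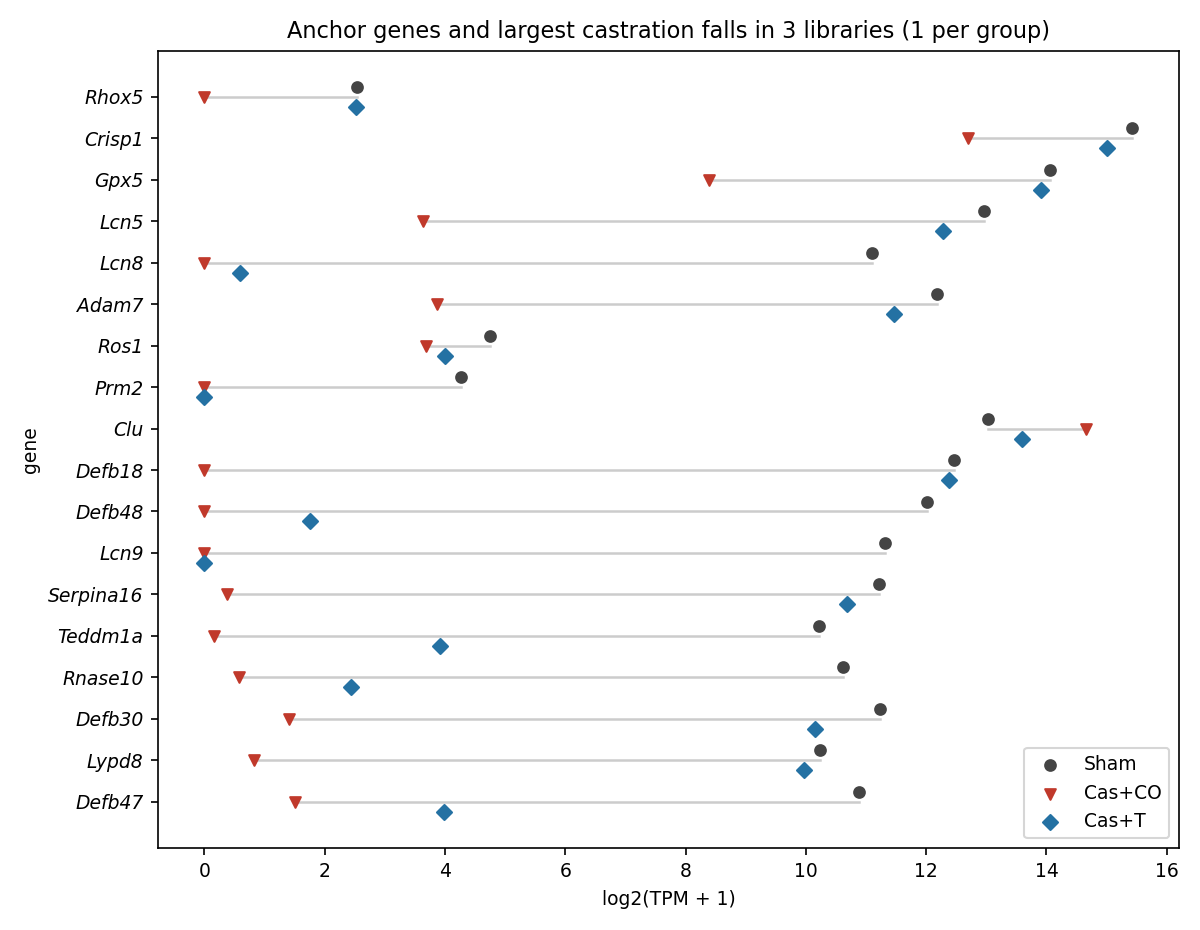
Expression of the anchor genes reported here and of the genes with the largest falls in Cas+CO against Sham, as log2(TPM + 1) on the horizontal axis, with 1 marker per library (circle, Sham; triangle, Cas+CO; diamond, Cas+T; markers are shifted vertically for legibility). Defb18 is back near Sham in Cas+T (5333 against 5648 TPM), while Lcn9 stays at 0.

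The first comparison, Cas+CO against Sham, asked what loss of the testes altered in the epididymis. No injection is recorded for the Sham group, so ratios over Sham may also hold an effect of the corn oil injections. Defb18 (ENSMUSG00000073735; GRCm38 chromosome 1, 18236473 to 18237443) was at 5648 TPM in Sham and Defb48 (ENSMUSG00000075574; chromosome 14, 62977524 to 62984510) at 4135 TPM; both are beta-defensins, antimicrobial peptides, and both were listed at 0 in Cas+CO. The lipocalins Lcn9 (ENSMUSG00000023210) and Lcn8 (ENSMUSG00000036449), carriers of small lipophilic molecules, were at 2552 and 2188 TPM in Sham and listed at 0 in Cas+CO. Serpina16, a serpin, was at 2389 TPM against 0.30, and Rnase10, a secreted ribonuclease family member, at 1562 against 0.48. Teddm1a (1195 against 0.12 TPM), Lypd8 (1199 against 0.77), Defb30 (2396 against 1.64) and Defb47 (1894 against 1.83) completed the 10 largest falls.

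Across the transcriptome, 16182 genes reached 1 TPM in Sham or Cas+CO, and on the log2(TPM + 1) scale 6075 of them were at least 2-fold higher and 1049 at least 2-fold lower in Cas+CO. The median log2 ratio over all these genes was 0.76, with every library fixed to the same total. When the libraries were instead brought to the same median over 12679 expressed genes, which lowered Cas+CO values by 0.80 and Cas+T values by 0.35 on the log2 scale, the counts were 2104 higher and 1898 lower. The share of higher genes among those past the limit was thus 85.3% as deposited and 52.6% after median scaling. Gene list medians below are therefore given relative to the median of all genes compared, and each is set against the range of 10000 random lists matched on expression.

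The secretory lists lay far below the random range. Among 10 lipocalins and related carriers, 8 were at least 2-fold lower and 2 higher, with a list median of −8.22 relative to all genes. Ptgds, which makes prostaglandin D2 and carries lipophilic ligands, was at 3268 TPM in Sham and 28.8 in Cas+CO. Of 36 beta-defensins, 29 were lower and 3 higher (list median −4.81). Of 25 serine protease inhibitors of the epididymis, 22 were lower and 1 higher (−4.40), including Spink2 (435 TPM against 0) and Spink10 (1026 against 1.44). Of 26 sperm maturation proteins, 22 were lower and 1 higher (−6.56), among them Cd52, a glycoprotein passed to the sperm surface, at 16184 TPM in Sham and 210 in Cas+CO. Initial segment genes, expressed in the part of the duct nearest the testis, were lower for 15 of 18 (−2.47), with Adam28 at 505 against 2.97 TPM. After median scaling 8, 31, 24, 23 and 16 members of these 5 lists were lower. Some genes stand in more than 1 list, such as Lcn8, Lcn9 and Defb48, which are also initial segment genes. Taking genes at 50 TPM or more in Sham that were at least 4-fold lower in Cas+CO gave 188 genes, which together held 20.7% of all TPM in Sham, 1.37% in Cas+CO and 15.2% in Cas+T.

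Cystatins, inhibitors of cysteine proteases, did not move as a block. Cst8 was at 238 TPM in Sham and 9.29 in Cas+CO and Cst11 at 2704 and 1214 TPM, while Cst3, the widely expressed cystatin C, was at 722 and 6254 TPM. The list median of 5 members was −1.74 relative to all genes, with 2 lower and 1 higher. Sperm and germ cell transcripts were lower for 13 of 19 (−2.95), as in Odf1, a sperm tail protein, at 27.3 TPM in Sham and 0 in Cas+CO. Seminal vesicle and prostate markers were lower for 6 of 7 (−2.74), with Mmp7, a matrix protease, at 66.3 against 0.80 TPM. Cholesterol synthesis genes lay at −1.28, with 6 of 18 lower and 1 higher (12 lower after median scaling), including Nsdhl (217 against 25.58 TPM) and Cyp51 (54.3 against 13.2 TPM). Cell cycle genes lay at −1.40, with 3 of 19 lower and 1 higher (8 lower after median scaling). This list had few abundant members: with a minimum of 10 TPM its unadjusted median turned from −0.63 to 0.64. Lists for protein folding in the endoplasmic reticulum (−0.86; 4 of 23 lower, 1 higher), antioxidant enzymes (−0.66; 6 of 28 lower, 2 higher) and nuclear oxidative phosphorylation (−0.73; 2 of 79 lower, 2 higher) were also below the random range. After median scaling 11, 13 and 17 of their members were lower and 1, 0 and 1 higher. In the last pair of lists most members lay within 2-fold as deposited, and the unadjusted medians, 0.11 and 0.04, turned below 0 under median scaling and under scaling without the 50 most abundant genes. Ribosomal protein genes lay at −0.31 relative to all genes yet above random lists of equally abundant genes, with 84 of 89 within 2-fold and an unadjusted median that turned from 0.45 to −0.33 under median scaling.

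Several lists of stromal, immune, fat and blood cell transcripts lay above the random range in Cas+CO against Sham, but those of smooth muscle, T and NK cells and neutrophils did not. All 13 adipocyte markers were at least 2-fold higher (list median 3.88 relative to all genes), with or without median scaling. Cfd, the adipokine adipsin, was at 6.21 TPM in Sham and 524 in Cas+CO, Car3 at 12.4 and 738, Fabp4 at 18.4 and 703, and Adipoq, which encodes adiponectin, at 1.93 and 124. Red blood cell genes were higher for 5 of 5 (4.09; 4 after median scaling), with the globin genes Hba-a1 at 36.4 and 1082 TPM and Hbb-bs at 28.3 and 1043 TPM. Of 22 fibroblast and matrix genes, 18 were higher and none lower (1.27; 12 higher after median scaling), among them Dcn at 55.8 and 881 TPM and Col3a1 at 16.9 and 304 TPM. Endothelial markers were higher for 12 of 13 (1.06; 8 after median scaling). Macrophage and myeloid markers were higher for 13 of 16 (0.96; 7 after median scaling), with the lysozyme gene Lyz2 at 34.1 and 496 TPM. MHC class II and dendritic genes were higher for 6 of 8 (2.12; 5 after median scaling), with Cd74, the invariant chain, at 19.3 and 208 TPM. All 11 B and plasma cell markers were higher (1.25; 9 after median scaling), led by the immunoglobulin light chain Igkc at 1.15 and 315 TPM. Mmp12, a macrophage elastase (0.15 and 161 TPM), Spp1, the matrix protein osteopontin (0.88 and 221 TPM), and Crisp3 (0.39 and 100.03 TPM) were among the 10 largest rises.

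Complement and acute phase genes were higher for 13 of 15 and lower for 1 (2.13; 11 higher after median scaling), with C3 at 5.83 and 180 TPM; the lower member, named after its value was seen, was Lcn2, at 1827 and 538 TPM. Interferon response genes were higher for 17 of 19 (0.85; 9 after median scaling), including Ifit3 at 0.42 and 30.9 TPM. Cell death and regression genes were higher for 14 of 23 (0.86; 9 after median scaling). They included Igfbp3, which binds insulin-like growth factors, at 1.52 and 65.8 TPM. Genes of clear cells, which acidify the lumen, were subunits of their proton pump and the transcription factors Dmrt2 and Foxi1, and were higher for 7 of 9 (1.16; 5 after median scaling), with Atp6v1b1 at 4.36 and 34.8 TPM. Steroid receptors and enzymes were higher for 8 of 15 and lower for 3 (0.53), a list that stayed above random lists as deposited but not after median scaling. Nr3c1, the glucocorticoid receptor, was at 8.47 and 32.8 TPM, and Srd5a2, a steroid 5-alpha reductase, at 84.7 and 26.3 TPM.

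The other lists lay within the random range as deposited, though water and ion transport and neutrophil markers lay below it after median scaling. These were smooth muscle (−0.51), general epithelial (−0.07), basal cell (−0.31), T and NK cell (0.53), neutrophil (0.34), nerve and Schwann cell (0.11), and Leydig and Sertoli cell markers (−0.09). The same held for androgen-responsive genes of other tissues (−0.22), polyamine enzymes (−0.45), water and ion transport (−0.35), immediate early genes (0.31) and mitochondrially encoded genes (−0.85). Single members still differed widely. Actg2, the enteric smooth muscle actin, was at 465 TPM in Sham and 32.7 in Cas+CO; the carbonic anhydrase gene Car4 was at 166 and 4.17 TPM; Ltf, lactoferrin, counted here as a neutrophil marker, was at 1102 and 60.2 TPM; and Cyp17a1, counted as a Leydig cell marker, was at 49.6 and 0.76 TPM.

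**Figure D2:**
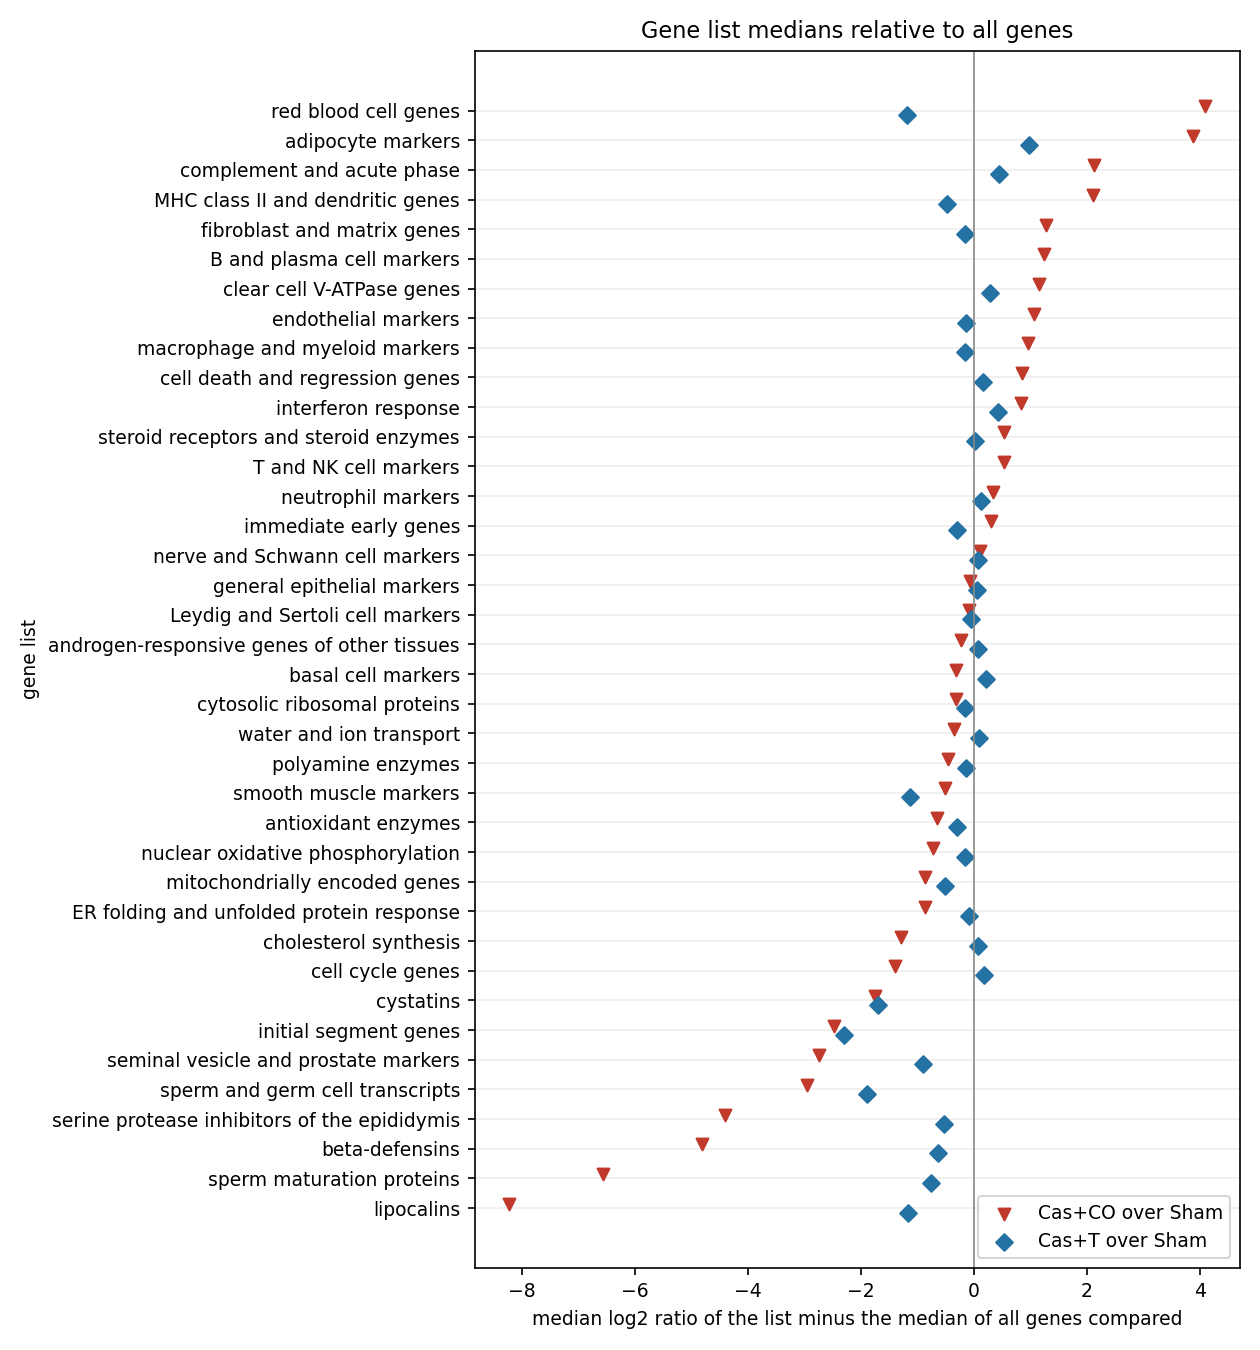
Median log2 ratio of each gene list minus the median of all genes compared, on the horizontal axis, for Cas+CO over Sham (triangles) and Cas+T over Sham (diamonds), with 1 library per group and no error estimate. Secretory lists such as lipocalins (−8.22) lie far to the left and adipocyte markers (3.88) to the right in Cas+CO; in Cas+T most lists lie near 0, whereas initial segment genes stay at −2.30. Lists with fewer than 3 members compared have no diamond.

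The second comparison, Cas+T against Cas+CO, asked what testosterone altered in castrated mice. Defb18 stood at 5333 TPM in Cas+T, Serpina16 at 1646, Ly6f at 1011, Lypd8 at 1005, Defb43 at 487, Teddm1b at 469, Clpsl2 at 457, Defb30 at 1131, Lcn5 at 4950 and Defb45 at 383; these were the 10 largest rises, and the highest of them in Cas+CO was Lcn5 at 11.45 TPM. Of 16165 genes compared, 1114 were at least 2-fold higher and 3786 lower in Cas+T, around a median log2 ratio of −0.46. After median scaling the counts were 1519 higher and 1928 lower, which moved the share of higher genes from 22.7% to 44.1%. Among the largest falls were Hba-a2 (514 TPM in Cas+CO, listed at 0 in Cas+T), Spp1 (221 against 0.56), Mmp12 (161 against 0.50), H2-T23 (89.8 against 0.18) and Igkc (315 against 4.16).

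By list, 27 of 34 beta-defensins, 21 of 24 serine protease inhibitors, 20 of 26 sperm maturation proteins and 5 of 8 lipocalins were at least 2-fold higher in Cas+T than in Cas+CO (29, 21, 21 and 6 after median scaling). Lower members of these lists numbered 3, 1, 2 and 1 (1, 1, 0 and 1 after median scaling). Initial segment genes were higher for 5 of 16 and lower for 4 (7 and 2 after median scaling). Their median of 0.73 relative to all genes (0.27 unadjusted) lay above the random range. Genes under 1 TPM in both castrated libraries are not compared here. Lcn8 and Lcn9, which stayed low in Cas+T, are thus absent from both the 8 lipocalins and the 16 initial segment genes. Cell cycle genes were higher for 11 of 21 and lower for none (1.53 relative to all genes; 12 higher after median scaling), with Cdk1, the mitotic kinase, at 8.25 TPM in Sham, 1.46 in Cas+CO and 14.4 in Cas+T. With a minimum of 10 TPM, the unadjusted median of this list turned from 1.07 to −0.18. Cholesterol synthesis genes were higher for 8 of 18 and lower for 1 (1.35; 15 higher after median scaling), and genes of protein folding in the endoplasmic reticulum for 6 of 23 (0.89; 9 after median scaling), including Manf at 252 and 599 TPM. In the other direction, all 13 adipocyte markers (−3.03), all 5 red blood cell genes (−5.18), 19 of 22 fibroblast and matrix genes (−1.16), 12 of 13 endothelial markers (−1.12) and 11 of 16 macrophage and myeloid markers (−1.40) were lower; after median scaling these counts were 13, 4, 13, 9 and 9. Smooth muscle markers, which had lain within the random range in Cas+CO against Sham, were lower for 8 of 15 (−0.59), but for only 2 after median scaling.

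Whether testosterone brought genes back was measured as the share of the log2 difference between Sham and Cas+CO that Cas+T made up. Of the 1049 genes lower in Cas+CO, 77.0% came back by at least 50%, 18.1% by under 25%, and the median return was 90.7%. Of the 6075 higher genes, 80.4% came back by at least 50%, 4.61% by under 25%, and the median return was 73.3%. After median scaling the shares back by at least 50% were 76.9% of 1898 lower genes and 85.9% of 2104 higher genes. Cas+CO enters both ratios, so chance alone gives some return: in simulated libraries with no difference between groups, 50.8% of the lower and 50.3% of the higher genes past the limit came back by 50%, but only about 94.8 and 93.2 genes passed it. The 15909 genes compared in both ratios held only 866 of the 1049 lower genes. Genes under 1 TPM in both Cas+CO and Cas+T were not compared, which leaves out genes that stayed low, such as Lcn8 and Lcn9. Among the 15909, 736 were lower after castration and then higher after testosterone, against 53.9 for independent lists and 13.6 in the simulation. For the opposite order the numbers were 3348, 1446 and 13.8. The shared library cannot be split, so part of the excess may come from it. The simulation also held no library-wide shift, whereas the median log2 ratio was 0.76 in Cas+CO over Sham and −0.46 in Cas+T over Cas+CO. Such a shift alone moves genes up and then down. Neither 13.8 nor the simulated 50.3% is therefore a chance value for the higher genes. The scatter was taken from Cas+T and Sham alone and given to Cas+CO as well. A Cas+CO library that stood apart for another reason would also give lower genes that come back. The simulated 13.6 and 50.8% leave out that case, so they set no full chance value for the lower genes either. The overlaps were not recomputed after median scaling.

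The return differed between groups of genes. Of the 188 abundant genes described above, 146 stood at 50% of Sham or more in Cas+T, 18 at 10 to 50%, and 24 under 10%. The counts by list that follow use the share of the log2 difference again. By that measure a gene with a deep fall can come back by 50% and still stand far under Sham. Lcn10, at 28.3% of Sham in Cas+T, and Ly6g5b, at 6.31%, both count as back. Serine protease inhibitors came back by at least 50% for 19 of 22 lower members, beta-defensins for 24 of 29, sperm maturation proteins for 17 of 22 and lipocalins for 6 of 8. Initial segment genes did so for 4 of 15, with 10 of the 15 back by under 25%, and sperm and germ cell transcripts for 2 of 13. Among lists raised after castration, 13 of 13 adipocyte markers, 12 of 12 endothelial markers, 11 of 11 B and plasma cell markers, 13 of 13 macrophage and myeloid markers and 17 of 18 fibroblast and matrix genes came back by at least 50%. No test of these differences between lists was run.

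The third comparison, Cas+T against Sham, asked what stayed apart from intact mice after testosterone. Lcn9 was listed at 0 in Cas+T, Lcn8 stood at 0.51 TPM, Defb48 at 2.37, Defb25 at 1.28 against 790 in Sham, and Rnase10 at 4.41; these were the 5 largest falls. Of 14631 genes compared, 756 were at least 2-fold higher and 402 lower in Cas+T, around a median log2 ratio of 0.30. After median scaling 308 were higher and 583 lower, so the share of higher genes went from 65.3% to 34.6% and the balance between directions rests on the scaling. The 5 largest rises were Hist2h2aa2, a histone gene with a neighbour that matches it over 528 of 528 aligned bases (0 in Sham and Cas+CO, 127 TPM in Cas+T), Zfp991 (0.10 and 13.5 TPM in Sham and Cas+T), Iapp, the hormone amylin (8.73 and 123 TPM), the T cell receptor segment Trav9-2 (0 and 11.04 TPM) and Ece1, endothelin converting enzyme (6.45 and 82.8 TPM).

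Initial segment genes had the lowest median of all lists in Cas+T against Sham (−2.30 relative to all genes; 10 of 18 lower, none higher), followed by sperm and germ cell transcripts (−1.88; 12 of 18 lower) and cystatins (−1.69; 3 of 5 lower). Red blood cell genes (−1.18; 2 of 5 lower), lipocalins (−1.16; 4 of 10 lower, 2 higher) and smooth muscle markers (−1.13; 3 of 15 lower) came next, with Actg2 at 47.7 TPM, 10.3% of Sham. After median scaling the lower members of these 6 lists numbered 13, 13, 3, 4, 7 and 8, and no lipocalin was higher. Seminal vesicle and prostate markers (−0.89), sperm maturation proteins (−0.75), beta-defensins (−0.64), serine protease inhibitors (−0.53), mitochondrially encoded genes (−0.51) and MHC class II and dendritic genes (−0.47) were below the random range too. Within the serine protease inhibitors the 2 lower members were Spint4 (1290 and 110 TPM) and Spint5 (633 and 144.8 TPM), and 5 were lower after median scaling. Smaller medians below that range belonged to immediate early genes (−0.30), antioxidant enzymes (−0.29) and nuclear oxidative phosphorylation (−0.15), with 13 of 14, 28 of 28 and 76 of 78 members within 2-fold as deposited (4 antioxidant enzymes were lower after median scaling); the unadjusted median of the first turned from −0.01 to 0.02 with a minimum of 10 TPM, and those of the other two, 0.01 and 0.14, turned below 0 under either scaling. Above the random range were adipocyte markers (0.98; 6 of 10 higher), complement and acute phase genes (0.46; 4 of 15 higher, with Lbp at 9.32 and 33.7 TPM), interferon response genes (0.42; 3 of 16 higher) and clear cell genes (0.28; 1 of 9 higher). After median scaling 4, 2, 2 and 0 of their members were higher.

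Genes that came back and genes that did not lay side by side in the same clusters, in GRCm38 coordinates of the GENCODE M21 annotation. The neighbours named here were chosen after their values were seen. On chromosome 2, Lcn8 (25653120 to 25656217) stood at 0.0233% of Sham in Cas+T, while Lcn5 (25657952 to 25661977), the next lipocalin on the same strand, stood at 62.3%, Lcn6 at 54.8% and Lcn10 at 28.3%. Lcn9 (25823153 to 25825537) was listed at 0. On chromosome 14, Defb48 stood at 0.0573% of Sham and Defb47 (62998077 to 63001160) at 0.784%, whereas Defb43 (63011771 to 63018088) stood at 123%, Defb30 at 47.2% and Defb42 at 77.9%. All of these genes were at 8.38% of Sham or less in Cas+CO.

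**Figure D3:**
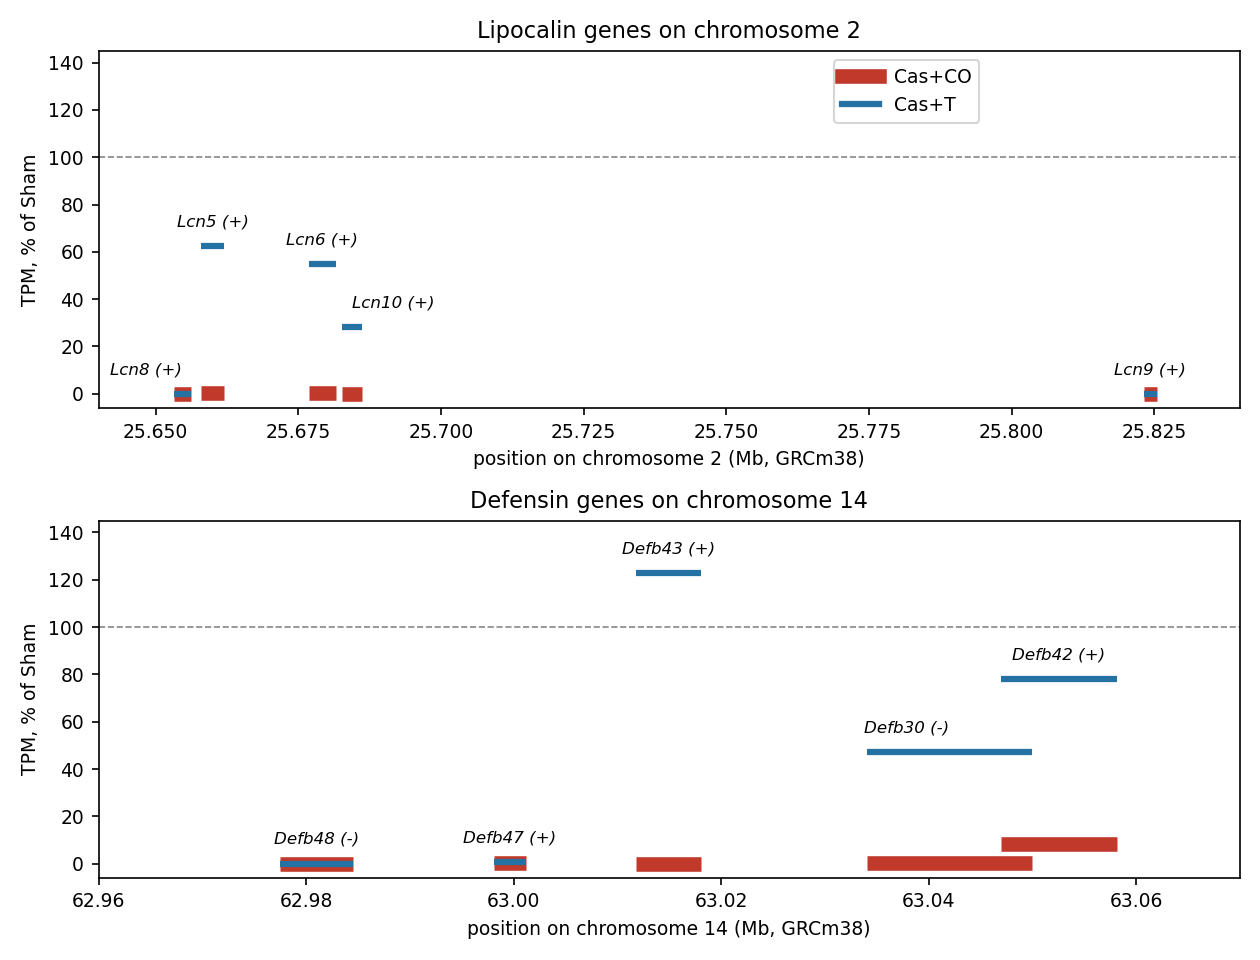
TPM as a percentage of Sham (vertical axis) over the annotated span of each gene (horizontal axis, Mb, GRCm38; strand in brackets) for 5 lipocalin genes on chromosome 2 and 5 beta-defensin genes on chromosome 14, with thick bars for Cas+CO, thin bars for Cas+T and a dashed line at the Sham level. Lcn8 and Lcn5 are neighbours, yet Lcn5 is at 62.3% of Sham in Cas+T and Lcn8 at 0.0233%.

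Several of the genes named belong to families of related genes or have annotated copies, and the files do not record how reads were divided among them. Sequences were aligned for only 2 pairs, Hist2h2aa2 with Hist2h2aa1 and mt-Co3 with its copy on chromosome 1, each identical over the aligned bases. Rpl30-ps9, a ribosomal protein pseudogene listed at 0 in Sham and Cas+T and at 314 TPM in Cas+CO, was the largest rise after castration and was not aligned to its relatives. In all, 48 genes were listed at 0 in 1 or 2 libraries and at 20 TPM or more in another.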

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

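All alternatives but the removal of genes listed at 0 were chosen before the data were examined; the cause of a difference was not tested unless the setting itself gives it. Of 92 recomputed counts and shares, 62 stayed within 1.5 times (counts) or within the 95% Wilson interval (shares) of the reported value. Dropping the 1 TPM minimum left the gene counts and shares as they were, since 2-fold with a pseudocount of 1 already requires 1 TPM, and gave 20 in place of 19 lists outside the random range in Cas+T over Sham. Keeping the highest row per symbol and removing sperm, blood, mitochondrial and ribosomal genes moved none beyond those limits. For named genes, 4501 of 4639 ratios moved by less than 1 on the log2 scale and none beyond 2-fold changed sign. The 138 that moved did so with a pseudocount of 0.1. The alternative for raw counts was not run, and no paired analysis was possible because each group has 1 library. Depth is unknown, so it is not known which low values lie above counting error.

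For Cas+CO against Sham, higher genes numbered 3551 and lower genes 549 with a minimum of 10 TPM, which leaves fewer genes, and 1230 and 413 at a 4-fold limit, which is stricter. Median scaling gave 2104 and 1898, and scaling without the 50 most abundant genes gave 4015 higher. For Cas+T against Cas+CO, the 10 TPM minimum gave 628 higher and 1821 lower, the 4-fold limit 403 and 859, and median scaling 1928 lower. For Cas+T against Sham, a pseudocount of 0.1 gave 1414 higher and 631 lower, the 10 TPM minimum 326 and 140, and the 4-fold limit 67 and 106; higher genes numbered 308 under median scaling and 451 without the 50 most abundant genes.

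The share of lower genes back by at least 50% (77.0%, interval 74.4 to 79.5%) was 87.4% with the 10 TPM minimum, 80.9% at the 4-fold limit, 85.1% without genes listed at 0 and 66.3% when a return of 75% was required. The share of higher genes (80.4%, interval 79.4 to 81.4%) was 75.6% with a pseudocount of 0.1, 77.5% with the 10 TPM minimum, 85.9% under median scaling, 84.7% without the 50 most abundant genes, 90.2% at the 4-fold limit and 47.5% for a return of 75%. The intervals treat genes as independent, which they are not.

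The number of lists outside the random range was 26 for Cas+CO over Sham, 28 for Cas+T over Cas+CO and 19 for Cas+T over Sham, and stayed within 1.5 times in every setting run. Of 656 recomputed list medians, 502 stayed as reported, 136 moved, of which 73 under median scaling, and 18 changed sign. Water and ion transport in Cas+T over Cas+CO (−0.01) became 0.013 with a pseudocount of 0.1, 0.011 with no minimum, 0.87 with the 10 TPM minimum, 0.76 under median scaling and 0.24 without the 50 most abundant genes. With the 10 TPM minimum, cell cycle genes became 0.64 in Cas+CO over Sham and −0.18 in Cas+T over Cas+CO, and immediate early genes 0.023 in Cas+T over Sham. Median scaling turned antioxidant enzymes (−0.69 in Cas+CO and −0.33 in Cas+T, over Sham), nuclear oxidative phosphorylation (−0.76 and −0.20) and ribosomal proteins (−0.33 in Cas+CO over Sham and 0.18 in Cas+T over Cas+CO). Without the 50 most abundant genes, antioxidant enzymes lay at −0.22 in Cas+CO and −0.18 in Cas+T over Sham, and nuclear oxidative phosphorylation at −0.29 and −0.044.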

Other observations

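Other clusters of related genes divided in the way of the lipocalins and the chromosome 14 defensins; these genes were picked after their values were seen. On chromosome 1, Teddm1a and Teddm2 stood at 1.18% and 0.962% of Sham in Cas+T, while Teddm1b stood at 173%. The annotated span of Teddm2 contains Teddm1a and Teddm1b on the opposite strand. With the strandedness unknown, Teddm2 may not be a case separate from Teddm1a. On chromosome 14, Rnase10 stood at 0.282% of Sham and its neighbours Rnase9, Rnase11 and Rnase12 at 57.6%, 132% and 126%. In the defensin cluster of chromosome 2, Defb25 stood at 0.162% and Defb45, the next defensin among those that reached 10 TPM, at 202%. The cystatin cluster of chromosome 2 followed another course: Cst8 and Cst11 were lower in Cas+CO than in Sham and lower again in Cas+T (238, 9.29 and 1.2 TPM for Cst8; 2704, 1214 and 296 TPM for Cst11). Cst3, in the same cluster, was at 722, 6254 and 771 TPM.

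Some genes were more than 2-fold higher in Cas+CO and came back by under 25% in Cas+T. The zinc finger genes Zfp979, Zfp984 and Zfp991, Tmsb15b1, a thymosin, and Wfdc17, a protease inhibitor, had the 5 largest differences of this kind, with 2.02 TPM or less in Sham, at least 10.43 TPM in Cas+CO and at least 7.42 TPM in Cas+T. Ece1 was higher at each step, with 6.45, 25.5 and 82.8 TPM. Klrb1c, listed here as a natural killer cell marker, was low in both castrated libraries, with 81.8, 1.39 and 3.27 TPM.

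The tests of explanations that follow were all chosen after the results were seen. Many stromal, immune, fat and blood markers, though not those of smooth muscle, stood higher in Cas+CO than in Sham. A fixed TPM total filled up after the loss of secretory transcripts would lift all genes alike, but the pooled median log2 ratio of 120 markers from all 11 lists of cells other than epithelium and germ cells was 1.72, above the random range of 0.65 to 0.98 (a first version pooled only 6 lists already seen to be high, and gave 2.11). A smaller share of epithelium would lift every other cell type alike. The upper quartile of the smooth muscle list (0.57) lay below the lower quartiles of the adipocyte, fibroblast, endothelial and macrophage lists, the lowest being 1.18. A smaller share thus cannot be the whole cause unless smooth muscle itself was lost. General epithelial markers were lower for 0 of 18 and higher for 4, with a median of 0.70 inside the random range. Their upper quartile (0.94) also lay below 1.18, so this list does not decide whether the share of epithelium fell. Fat and blood carried along with a smaller organ may account for the adipocyte (median 4.64) and red blood cell lists (4.86), whose most abundant genes, Car3 and Hba-a1, reached 738 and 1082 TPM; with 1 library per group this cannot be told apart from a change in the tissue. An effect of androgen loss on these cell types remains open and untested.

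Of 15 initial segment genes at 10 TPM or more in Sham, 6, among them Ggt1 at 126% and Srd5a2 at 124%, were at 50% or more in Cas+T. Not all of the 6 had come back: Spry1 was at 152% of Sham in Cas+CO and 59.8% in Cas+T. Ros1 went only from 46.0% to 57.9%. Another 7 lay under 10% of Sham in both castrated libraries (Adam28, Cst8, Defb48, Etv5, Lcn8, Lcn9 and Ovch2). That genes which fell farthest come back least, whatever their list, cannot be told apart from an effect on these genes: of 52 other genes that fell as far, 26.9% lay under 10% of Sham in Cas+T (Wilson interval 16.8 to 40.3%), against 3 of 128 that fell at least 4-fold but less far, and the cut was the median of members picked for being low. This measure was the last of 3 versions, each set after the one before had been seen, and its rule was changed once more to take in the 128 genes: at first, 105 of 139 genes lowered as far as the median of all 15 members stood at 50% of Sham or more in Cas+T (67.8 to 81.9%), and next 32 of the 52 did (48.0 to 73.5%). Only listed genes were left out of the 52, so unlisted genes of the segment may be among them. They include Defb47, a cluster neighbour of Defb48, and mt-Co3, whose values near 0 are discussed below. Loss of the initial segment from the dissected tissue could also leave these genes low. It cannot be told apart from a change within the segment, because no library of the segment alone was analysed. The hypothesis that these genes depend on testicular factors reaching the duct through its lumen, which injected testosterone does not replace, was not tested; mice with the duct cut off from the testis and androgen kept would decide it.

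Some genes were listed at or near 0 in certain libraries and high in another. For mt-Co3 (93.6 TPM in Sham, 0.25 in Cas+CO and 0.23 in Cas+T) a candidate explanation is the division of reads with Gm28437, a copy on chromosome 1: the transcripts share 783 of 783 aligned bases, but the test cannot tell, because the copy held 27012 of the 27105 TPM of the pair in Sham and the log2 ratio of the sum, −0.38 in Cas+CO over Sham, would stay within 2-fold even if only mt-Co3 were lost. Hist2h2aa2 and its neighbour Hist2h2aa1 share 528 of 528 aligned bases, and their sum had a log2 ratio of 0.68 in Cas+T over Sham while Hist2h2aa2 alone was listed at 0 in Sham and at 127 TPM in Cas+T. For this pair the test could have failed, as a gain in Hist2h2aa2 beside an unaltered copy would give 1.14. It was run for Cas+T over Sham only. Hist2h2aa2 was also listed at 0 in Cas+CO, where the sum was 63.5 TPM against 168 in Cas+T, more than 2-fold apart. Reads assigned to either copy could thus account for the difference from Sham but, by the same limit, not for all of that from Cas+CO. How reads were assigned is not shown. A biological explanation was not tested for either pair.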
